A study of Homo sapiens with 6 samples.

How the data were processed

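Total RNA from A375 melanoma cells was sequenced in 6 libraries, 3 of cells with a control hairpin (shControl) and 3 of cells with an MMP9 hairpin (shMMP9), and groups and replicate numbers were taken from the labels. Per the submitters' processing notes, STAR 2.6.1d and Partek were used with the hg38 build. The counting method, annotation, strand setting, library kit and filter are not given in the sources used here. The deposited table holds 18539 genes with 1 value per library on a log2 scale. The name of the table calls these values counts, but the values themselves showed log2(scaled count + 1): back on the linear scale, each library's 75th percentile was the same to 3 digits (45.4) and most values were whole multiples of 1 step. Those steps gave estimated reads, of which 64.5 to 67.8% per library were whole within 0.01 reads. The rest are fractions, as when reads are divided between genes, so near-identical genes are uncertain. Summed over listed genes the libraries held 21854113 to 28005536 estimated reads, and genes with a symbol starting with MT- held 0.62 to 1.79% of them. Every listed gene had at least 1 estimated read in each library and at least 11 in 1 of them, so a gene with no read in some library cannot be seen here. Symbols of 23 genes had been turned into dates and were left unnamed.

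The design planned a quasi-likelihood test of raw counts, with a test on normalized values to take its place if the table held none. As the values are not raw counts, edgeR and DESeq2 were not used, and the second test was run: limma 3.58.1 in R 4.3.3, with an empirical Bayes variance trend, on the deposited log2 values with their pseudocount of 1 and no further scaling. The upper-quartile scaling of the deposited values sets the balance of rises and falls, and the closing section gives other scalings. Genes needed 10 reads at the median depth in 3 libraries and 15 reads in total, which kept 17194 and removed 1345. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05 and, for size, a log2 change of 1. On simulated data for this comparison, 200 of 17194 genes were changed, all drawn from well-expressed genes. Every gene was given the same spread between libraries (dispersion 0.01). The test recovered 86.6% of genes changed by 1.5-fold and 100% of those changed by 2-fold or by 4-fold, and it called 11 unchanged genes. These rates do not carry over to weak genes, nor to the real comparison, in which 57.5% of tested genes were called.

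Replicates were compared before averaging. Chi-square per gene between libraries of a group ran from 2.64 to 17.3 on estimated reads, above sampling noise for every pair, so none was treated as a duplicate. The highest values were between shControl replicate 1 and the other shControl libraries.

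Gene lists (29, with 932 members, of which 845 were found in the table, 27 of them under an older symbol), the rule for named genes and the tests of genes and lists were fixed before the data were examined. Tests of chromosomes, of their arms and bins, and of gene families were added later, and the closing section says which were chosen after their results were seen. The rule takes MMP9, the 12 largest rises and 12 largest falls with an adjusted p under 0.05, a mean CPM (counts scaled to the library total) of 5 or more, a gene symbol that is no locus name and groups that do not overlap, and up to 4 members of each list with the smallest adjusted p. Genes named outside it are marked in the text, and some genes that the rule takes are not reported here. Lists with 5 or more tested members were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry, whose test asks only whether the genes of a list move one way on balance. Symbols were matched to GENCODE release 29 on GRCh38 for 99.5% of genes, and its transcripts gave the hairpin's target site, 3' untranslated regions, GC content and length. Chromosome arms were parted at the widest interval without genes, with the acrocentric chromosomes taken as long arms. Figures were drawn with matplotlib 3.10.9.

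Alternatives planned beforehand were the replicate number as a block, each library left out, median-of-ratios and total-read scaling, no low-count filter, limma-voom on estimated reads and a threshold of 0.01. Pseudocounts of 0.25 and 4, no variance trend, a minimum mean scaled count of 5 and leaving out chromosomes 13 and 18 were chosen after seeing the data.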

Results

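The series asks how the transcriptome of melanoma cells responds to depletion of matrix metalloproteinase 9 (MMP9), a secreted gelatinase that its title links to clipping of histone H3 tails. RNA was sequenced from A375, a human malignant melanoma line that carries an activating BRAF mutation. The cells had been infected with lentivirus carrying either a control short hairpin RNA (shControl, 3 libraries) or a hairpin against MMP9 (shMMP9, 3 libraries) and selected with puromycin. The listed genes held an estimated 25103297, 28005536 and 24319956 reads in shControl replicates 1 to 3, and 25895672, 21854113 and 23483950 in shMMP9 replicates 1 to 3. Levels below are gene counts scaled to a common upper quartile, given as mean ± SD with n = 3 per group. Fold changes are differences of log2(scaled count + 1), shMMP9 minus shControl, which understate the change of weakly expressed genes. No label says that replicates came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

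The hairpin targets CATTCAGGGAGACGCCCATTT, which lies in exon 4 of the 13 exons of MMP9 (ENSG00000100985.7), inside the coding sequence, at chromosome 20, 46010992 to 46011012 on the plus strand of GRCh38. The gene spans 46008908 to 46016561. The full target was found in 1 of 206694 annotated transcripts, that of MMP9. MMP9 stood at 26.4 ± 2.18 in shControl and 15.9 ± 1.31 in shMMP9 (SD, n = 3), a level 0.605 times that of the control. It fell by 0.69 on the log2 scale (SE 0.0847, adjusted p = 1.25e-05, limma), and every shMMP9 library lay below every shControl library.

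**Figure D1:**
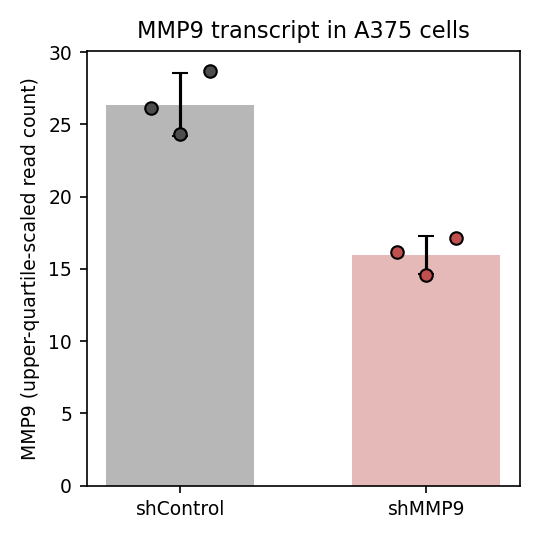
MMP9 level in each library, as an upper-quartile-scaled read count on a linear axis from 0. Bars are group means, error bars the SD and points the 3 libraries of each group. The shControl mean is 26.4 and the shMMP9 mean 15.9.

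As groups, targets of YAP and TEAD, genes of the invasive melanoma state, inflammatory, sterol synthesis and mitochondrially encoded genes were lower in shMMP9, and MAPK output, antigen presentation and melanocyte differentiation genes were higher. All of these lists but the mitochondrially encoded one also held members that passed in the other direction. In the pigmentation and melanocyte differentiation list 12 of 24 tested members rose and 7 fell. The group calls were made by camera with a preset correlation between genes, and none was made with an estimated one (lowest adjusted p = 0.235 with an estimated correlation). Of 17194 genes tested, 4304 rose (25%) and 5584 fell (32.5%) at an adjusted p under 0.05. The excess of falls depends on the scaling, with 5013 rises and 4875 falls under median-of-ratios scaling and 4988 and 4898 under total-read scaling. At a change of 2-fold or more, 553 rose and 852 fell, counts that depend on the pseudocount (844 and 1407 with one of 0.25, 321 and 425 with one of 4) and were 1047 and 1682 with limma-voom. The 2 groups did not overlap for 10777 genes, against 1719 (10%) by chance. The first principal component held 86.9% of the variance and separated the groups.

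Among genes at a mean CPM (counts scaled to the library total) of 5 or more, MUC5B, a gel-forming mucin, had the largest rise on the log2(scaled count + 1) scale, from 3.43 ± 0.0800 to 49.8 ± 3.80, a log2 fold change of 3.52 (SE 0.0853, adjusted p = 2.18e-12). The ratio of means was 14.5 for MUC5B, 15.2 for NTSR1 and 27.5 for PRSS3. The neurotensin receptor NTSR1 rose from 2.13 ± 0.459 to 32.3 ± 2.68, and the mesenchymal homeobox gene PRRX1 rose from 12.9 ± 1.27 to 133 ± 9.96. RXRG, a retinoid receptor of neural crest-like melanoma cells, rose by 3.12 and TFAP2B, a neural crest transcription factor, by 2.90. PDK4, which restrains pyruvate dehydrogenase, rose from 14.99 ± 0.212 to 129 ± 4.42, with a log2 fold change of 3.03. IGFBP5, an insulin-like growth factor binding protein, rose by 2.94 and the calcium-binding protein gene S100A1 by 2.74. PRSS3, a trypsinogen, rose by 3.23 and AKR1C2, an aldo-keto reductase, by 3.01. Both have close homologues that could share reads, so these values are uncertain. SHISA2 rose by 2.84 and lies on chromosome 13, whose genes at a mean CPM of 5 or more had a median log2 fold change 0.30 above that of all such genes. SERPINB2, a plasminogen activator inhibitor, rose by 2.74 although it lies on chromosome 18, whose median, over the same range of CPM, differed from that of all such genes by -0.43.

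BASP1, a membrane-bound signalling protein gene, had the largest fall by the same measure. It went from 116 ± 0.382 to 0.144 ± 0.0566, a log2 fold change of -6.68 (SE 0.0892, adjusted p = 2.01e-14), with 5, 2 and 5 estimated reads left in the shMMP9 libraries. MME, which encodes the cell-surface peptidase neprilysin, fell from 181 ± 17.3 to 0.783 ± 0.153 (log2 fold change -6.67). The hair keratin gene KRT81 fell from 1173 ± 106 to 44.8 ± 2.77, and shares much of its sequence with neighbouring keratin genes, so its value is uncertain. The cytokine gene IL6 fell from 51.1 ± 4.46 to 1.19 ± 0.314 (log2 fold change -4.58), and the chemokine gene CCL3 from 21.2 ± 2.46 to 0.254 ± 0.0426. TMPRSS15, which encodes enteropeptidase, had a log2 fold change of -4.39, and SH3GL2, which encodes an endocytic protein, one of -4.21. The laminin gene LAMA1 had one of -4.21 and lies on chromosome 18. The sperm protein genes SPANXA1, SPANXA2, SPANXB1 and SPANXD had values of -5.22, -4.88, -4.45 and -4.14. These X-linked copies are nearly identical and share reads, so the share of each is uncertain.

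**Figure D2:**
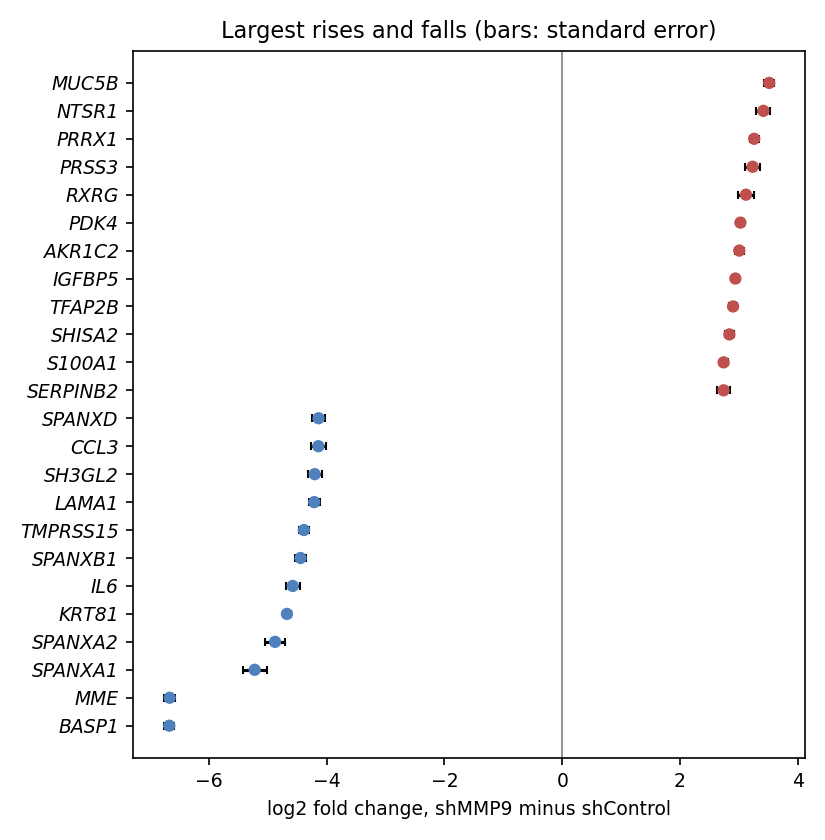
Log2 fold change (shMMP9 minus shControl, horizontal axis) of the 12 largest rises and 12 largest falls on this scale among genes at a mean CPM of 5 or more. Points are fitted values and bars their standard errors. The rises reach 3.52 for MUC5B and the falls -6.68 for BASP1.

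Of the 29 gene lists, 3 were called higher and 7 lower by camera with its preset correlation of 0.01. With a correlation estimated from these libraries none was called, with a lowest adjusted p of 0.235, while 5 lists had an unadjusted p under 0.05. Among the called lists, the estimate lay below the preset for the invasive (0.005), pigmentation (-0.035) and p53 (-0.02) lists. For these a higher correlation is not what ended the call. Member counts below use the adjustment over all genes tested. Adjusted over the list alone, they were the same for 19 lists and differed by 1 gene in the other 10.

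Targets of YAP and TEAD, the transcription regulators of the Hippo pathway, were lower as a group (camera adjusted p = 5.84e-05, adjusted p = 0.235 with an estimated correlation). Of 24 tested members 18 fell and 4 rose. The matricellular genes CYR61 and CTGF had log2 fold changes of -2.60 and -1.83, and the ankyrin repeat gene ANKRD1 one of -2.70. AMOTL1, which encodes a YAP-binding angiomotin, rose by 1.38. The list of the dedifferentiated and invasive melanoma state was also lower (camera adjusted p = 0.000284, adjusted p = 0.235 with an estimated correlation). As fixed, both lists hold CYR61, CTGF, AXL, CRIM1, NT5E and TGFB2, so these calls are not independent. The invasive list also shares IL6 and CXCL8 with the inflammatory list below. Of its 33 tested members 22 fell and 7 rose, with AMIGO2, an adhesion molecule gene, at -2.06.

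Inflammatory cytokines and NF-kB targets were lower (camera adjusted p = 0.000626, adjusted p = 0.477 with an estimated correlation), with 23 of 35 members falling and 6 rising. Adjusted over the list alone, 24 fell. IL1B, an inflammatory cytokine gene, fell from 136 ± 11.01 to 9.79 ± 0.391, and TNFAIP2, a TNF-induced gene, had a log2 fold change of -1.54. TRAF1, a signalling adaptor induced by NF-kB, rose by 2.73.

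Enzymes of cholesterol and fatty acid synthesis were lower (camera adjusted p = 3.43e-06, adjusted p = 0.235 with an estimated correlation). Of 31 members 25 fell and 2 rose. DHCR7, the last enzyme of cholesterol synthesis, had a log2 fold change of -1.65, and SREBF2, the sterol-responsive transcription factor, one of -1.21. The desaturase gene SCD stood at -0.91 and ACACA, acetyl-CoA carboxylase, at -0.90.

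Of the 13 mitochondrially encoded genes 12 fell and none rose (camera adjusted p = 3.43e-06, adjusted p = 0.477 with an estimated correlation). The estimated correlation between these genes was 0.659, far above the preset. They therefore cannot be counted as 13 separate observations, as the test with the preset correlation nearly does. The cytochrome oxidase gene MT-CO2 went from 1284 ± 59.3 to 321 ± 18.3, and MT-CO1 from 4557 ± 294 to 1446 ± 62.3. MT-ND4 and MT-CO3 had log2 fold changes of -1.66 and -1.22. All genes with a symbol starting with MT-, a wider set than these 13, held 1.64 to 1.79% of the reads in shControl libraries and 0.62 to 0.71% in shMMP9 libraries.

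Genes of mitosis and the G2/M phase were lower by smaller amounts (camera adjusted p = 0.00356, adjusted p = 0.477 with an estimated correlation). Of 40 members 22 fell and 2 rose, and the list median was -0.24. CDC20, an activator of the anaphase-promoting complex, stood at -0.93, the kinase gene AURKB at -0.61, ANLN at -0.49 and TPX2 at -0.38. Targets of p53 were lower (camera adjusted p = 0.0418, adjusted p = 0.252 with an estimated correlation), with 15 of 26 falling and 4 rising. GDF15, a stress-induced cytokine gene, stood at -2.54, the kinase gene PLK2 at -1.29, the cell cycle inhibitor CDKN1A at -1.05, and PMAIP1, a pro-apoptotic gene on chromosome 18, at -1.11. This call ended without the genes of chromosomes 13 and 18 (adjusted p = 0.0777) and without a variance trend (adjusted p = 0.0852), with the other 14 settings of the camera test between 0.0299 and 0.0461.

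Output genes of the MAPK pathway were higher (camera adjusted p = 0.00356, adjusted p = 0.477 with an estimated correlation). Of 25 members 16 rose and 8 fell, and 17 rose when adjusted over the list alone. EGR1, an immediate early transcription factor, rose from 10.1 ± 0.483 to 72.8 ± 2.52. The feedback inhibitors SPRY4 and DUSP6 rose by 2.04 and 1.44, and SPRY2, on chromosome 13, by 1.46. Chosen after their values were seen, FOSL1, MYC and CCND1 of this list had log2 fold changes of -1.40, -1.02 and -0.60.

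The pigmentation and melanocyte differentiation list was higher (camera adjusted p = 0.014, adjusted p = 0.247 with an estimated correlation), with 12 of 24 members rising and 7 falling. The receptor gene ERBB3 rose from 84.1 ± 4.27 to 349 ± 2.84, the endothelin receptor gene EDNRB, known from the neural crest and on chromosome 13, by 2.31 and GAS7 by 1.75. Chosen after their values were seen, MITF, the master regulator of pigment cells, had a log2 fold change of -0.34, and the melanosome gene PMEL one of 0.03 that did not pass the test.

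Antigen presentation genes were higher (camera adjusted p = 0.00215, adjusted p = 0.252 with an estimated correlation). Of 25 members 14 rose and 5 fell, and 6 fell when adjusted over the list alone. CD74, the invariant chain of class II molecules, rose from 671 ± 7.93 to 1516 ± 17.5, and CIITA, the class II transactivator, rose by 1.22. HLA-B and HLA-DRA rose by 1.20 and 1.15, with values that are uncertain because HLA genes are alike and vary between people.

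**Figure D3:**
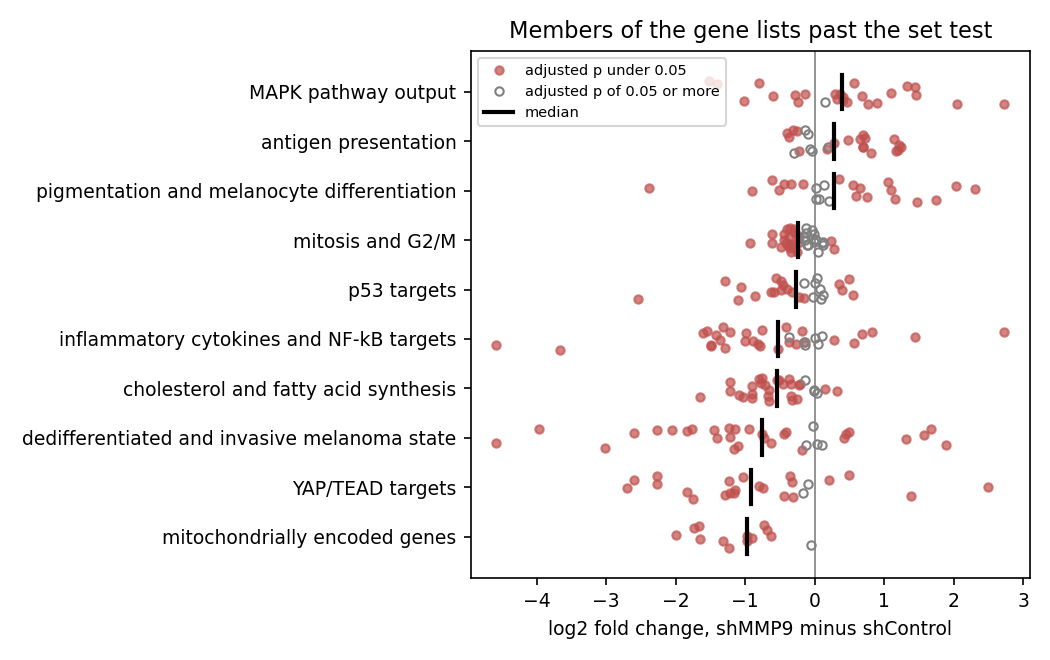
Log2 fold change (shMMP9 minus shControl, horizontal axis) of each tested member of the 10 called lists. Filled points passed the test over all genes, open points did not, and black lines are list medians. Medians run from -0.98 for the mitochondrially encoded genes to 0.40 for MAPK pathway output, and each list but the mitochondrially encoded one holds members that passed in both directions.

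The other 19 lists were not called by camera with the preset correlation. Among proteases and their inhibitors 16 of 39 rose and 18 fell (camera adjusted p = 0.589), with the plasminogen activator gene PLAT at 2.22, the inhibitor TIMP3 at 2.18, the membrane-bound MMP16 at 1.98 and ADAMTS12 at -1.89. Of 41 extracellular matrix genes 14 rose and 25 fell (adjusted p = 0.0975), with LAMA4 at 2.19, COL9A3 at 1.88 and LOXL2 at -1.45. Of 29 cell adhesion receptors 17 rose and 10 fell (adjusted p = 0.104), with the integrins ITGA6 at 1.65, ITGB3 at 1.21 and ITGB4 at -2.26, and L1CAM at -1.35. The epithelial-mesenchymal list had 7 rising and 10 falling of 20 (adjusted p = 0.589), with S100A4 at 2.29 and CDH2, on chromosome 18, at -0.62. Of 45 growth factors and receptors 20 rose and 19 fell (adjusted p = 0.595), with TGFA at 1.74 and FLT1, on chromosome 13, at 2.69. Of 24 immediate early genes 11 rose and 9 fell (adjusted p = 0.45), with EGR3 at 2.42 and FOSL2 at -1.61.

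The series title concerns clipping of histone H3 tails, which transcript levels do not measure. Of 60 replication-dependent histone genes fixed beforehand, 19 were tested, at a median scaled count of 1.15. Among these 19, 2 rose and none fell (camera adjusted p = 0.589), and 1 rose when adjusted over the list alone. HIST1H2AG stood at 0.62 (adjusted p = 0.00239) and HIST2H2BF at 0.42 (adjusted p = 0.0255), at means of 1.53 or less, and reads shared within the family leave both uncertain. The HIST2H2BF call ended without shControl replicate 2 (adjusted p = 0.0946), shMMP9 replicate 1 (adjusted p = 0.112) or shMMP9 replicate 2 (adjusted p = 0.0802), and its log2 fold change was 0.79 with limma-voom, 0.64 with a pseudocount of 0.25 and 0.18 with one of 4. Of 55 histone acetylation and methylation enzymes 24 rose and 15 fell (adjusted p = 0.0879). This list was called higher with median-of-ratios scaling (adjusted p = 0.0455) and with total-read scaling (adjusted p = 0.0447), against an adjusted p = 0.533 with an estimated correlation. Its members included the deacetylase genes HDAC4 at 1.58 and HDAC9 at -1.30, the methyltransferase gene NSD2 at -0.78 and the acetyltransferase gene EP300 at 0.81.

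Of 42 DNA replication genes 18 rose and 8 fell (adjusted p = 0.0975, adjusted p = 0.491 with an estimated correlation). The adjusted p was 0.0455 with median-of-ratios scaling and 0.0515 with total-read scaling. Members included GINS3 at 1.20 and CDT1 at -0.82. Of 23 G1 cyclins, kinases and inhibitors 10 rose and 7 fell (adjusted p = 0.307), with RBL1 at 1.01 and E2F5 at -1.15. Of 32 apoptosis regulators 9 rose and 13 fell (adjusted p = 0.589), with BOK at -1.40 and BID at -0.90. Of 37 interferon response genes 11 rose and 19 fell (adjusted p = 0.712), with IFITM2 at -0.96 and CMPK2 at 1.11. Of 32 hypoxia and glycolysis genes 10 rose and 16 fell (adjusted p = 0.307), with CA12 at -2.16 and PFKFB3 at 0.91. Of 31 genes of the unfolded protein and integrated stress responses 13 rose and 9 fell (adjusted p = 0.173), with the cystine transporter gene SLC7A11 at 2.41, ASNS at -1.13 and DNAJC3, on chromosome 13, at 0.97. Of 50 cytosolic ribosomal protein genes 13 rose and 10 fell (adjusted p = 0.233), and the list was called higher without shControl replicate 1 (adjusted p = 0.0093). With all libraries it had an adjusted p = 0.712 with an estimated correlation and an adjusted p = 0.717 with fry. RPL3 stood at -0.61 and RPS12 at 0.46.

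None of the lists of other cell types was called by camera. Fry, which does not compare a list with other genes, called all 4: keratinocyte (adjusted p = 0.000868), fibroblast (adjusted p = 0.000501), endothelial (adjusted p = 0.00506) and leukocyte (adjusted p = 0.0266), the last in the upward direction against a downward one in camera. Keratinocyte markers had 4 rising and 2 falling of 9 (adjusted p = 0.307), with KRT14 going from 4.04 ± 0.482 to 19.7 ± 1.53. Fibroblast markers had 2 rising and 6 falling of 8 (adjusted p = 0.39), with COL1A1 at -2.23 and PRRX1, named above, also in this list. Leukocyte markers had 1 rising and 3 falling of 7 (adjusted p = 0.668), with LYZ at 1.29, and endothelial markers 2 rising and 3 falling of 8 (adjusted p = 0.668), with TIE1 at -3.20.

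Genes shifted together on 2 chromosomes. Among 203 chromosome 13 genes at a mean CPM of 5 or more, 119 rose and 23 fell, and among 178 on chromosome 18, 18 rose and 130 fell. Their medians differed from that of all such genes by 0.30 and -0.43, outside the range of 10000 random gene sets of the same size. Of the other nuclear chromosomes only chromosome 19 lay outside that range, with a shift of -0.09 against a lowest random value of -0.08. Its shift was -0.036 after a trend with GC content and transcript length was removed. Leaving out chromosomes 13 and 18, 4124 genes rose and 5342 fell.

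**Figure D4:**
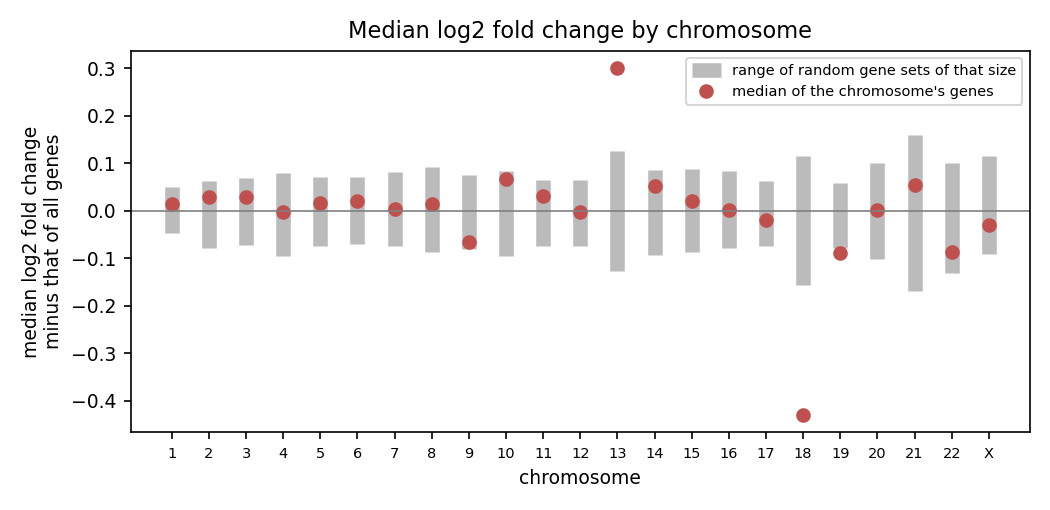
Median log2 fold change of the genes of each nuclear chromosome minus that of all genes at a mean CPM of 5 or more (vertical axis, log2 units). Points are chromosomes and grey bars the range of 10000 random gene sets of the same size. Chromosome 13 lies at 0.30 and chromosome 18 at -0.43.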

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

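Pseudocounts of 0.25 and 4, no variance trend, a minimum mean scaled count of 5 and leaving out chromosomes 13 and 18 were chosen after seeing the data, and the other settings were planned. MMP9 fell in all 16 alternatives, with log2 fold changes of -0.61 to -0.75, each past the threshold. Of the 9888 calls, 86.7 to 94.5% remained without any 1 library and 74.4 to 99.5% under other settings, the lowest with the minimum mean of 5, which tests fewer genes, and each kept its direction. The counts at 2-fold or more depend on the pseudocount: 844 rose and 1407 fell at 0.25, and 321 and 425 at 4. They were 1047 and 1682 with limma-voom, and 496 fell with the minimum mean. Scaling set the balance: 43.5% of calls were rises in the deposited scaling, 50.7% (5013 against 4875) with median-of-ratios and 50.5% with total reads. Lists called higher and lower numbered 0 and 0 with an estimated correlation and 13 and 14 with fry, and median-of-ratios scaling called 5 higher, adding DNA replication and histone enzymes (total reads added only the latter); the cause was not tested. The 126 other named genes were chosen for large changes or small p-values in these same data, which favours stable calls. Of their 1996 alternative values, 1993 kept direction and call, and none reversed. The other 3 were HIST2H2BF without shControl replicate 2 (adjusted p = 0.0946), shMMP9 replicate 1 (0.112) or shMMP9 replicate 2 (0.0802), in a range from 0.00795. Deviations of same-numbered libraries from their group means correlated at 0.11, -0.24 and 0.01, and the replicate block gave 4211 rises and 5486 falls. With 3 libraries per group these correlations cannot decide whether the replicate numbers pair the samples, and no label says so. DESeq2 was planned and not run, because the values are not counts. Depth limits the weakest genes, with under 10 estimated reads.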

Other observations

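The tests of chromosome bins and of arms outside chromosomes 13 and 18, the share of calls that a copy-number cause would need, and the choice of gene families below, were made after the results were seen. Gene families formed from the letters of a symbol gave no further theme: none of 248 families with 8 or more tested members passed camera (lowest adjusted p = 0.333, or 0.981 with an estimated correlation). Picked after their values were seen, the ADAMTS proteases had 11 of 16 members falling and 3 rising, the cadherins (CDH) 8 of 14 falling and 1 rising, and the SOX transcription factors 7 of 12 rising and 2 falling.

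The first pattern is the number of genes past the threshold, 9888. The 6 libraries can be split into 3 and 3 in 10 ways. Of these 1, the real one, gave as many, and the highest other split gave 1 gene. Every other split mixes shControl and shMMP9 libraries, so the group difference widens the spread within each side and few calls were bound to follow. The splits, also too few for a share under 0.05, cannot decide whether the calls arose by chance. A general lowering of genes matching bases 2 to 8 of the hairpin's guide is argued against. The 1276 genes with the matching site GCCCATT in their 3' untranslated region had a median 0.021 above that of 11525 genes without it, matched for length and expression (one-sided permutation p = 0.941). The guide was taken as the exact reverse complement of the target. A median over these genes cannot exclude repression of a few of them. Other guide ends, the other strand and the control hairpin were not tested. The bound set beforehand against copy number was no arm with a median 0.2 or more from that of all genes. It was not met by 3 arms (13q, 18p and 18q), which held 4.0% of called and 3.4% of tested genes. The largest shift of any other arm of 50 or more tested genes was 0.088. Without chromosomes 13 and 18, 9466 calls remained. For these calls the arm values argue against a copy-number difference of whole arms, but not against one of smaller segments. The partial fall of MMP9, to 0.605 times the control level, stays open as an explanation. So does any other difference between the separately infected and selected cell populations, with 1 hairpin, since each follows the groups.

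The second pattern is the shift on chromosomes 13 and 18. A copy-number difference between the cell populations may account for it. Bins of 10 Mb were used where they held 10 or more genes at a mean CPM of 5 or more. All 8 such bins on chromosome 13 were shifted up, by 0.17 to 0.55, and all 8 on chromosome 18 down, by -0.37 to -0.55, with a chromosome 18 shift of -0.43. Parts of chromosome 13 with fewer such genes were not assessed. A trend with GC content or transcript length is argued against, since the smaller of the 2 shifts was still 0.27 after that trend was removed. DNA copy number was not measured here, and whether such a difference arose with the hairpin or by selection of clones cannot be read from these values.

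The third pattern is the lower level of mitochondrially encoded genes. A wider fall of respiratory chain transcripts is argued against, since 85 nuclear-encoded subunits had a median of 0.024 (quartiles -0.19 and 0.16), with 21 rising and 25 falling. Reads moved to the 13 listed nuclear copies of these genes are argued against too. The summed level of these copies went from 122 to 48.7, a change of -0.85% of the fall. Copies with no read in some library are not listed, so reads moved to those cannot be excluded. Any other difference that follows the groups, such as RNA handling or mitochondrial content, was not tested.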
